A study of Triticum aestivum with 12 samples.

How the data were processed

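RNA abundance was measured on 12 Affymetrix wheat arrays, each hybridised with RNA from the roots of 1 sample of winter wheat seedlings. Per the labels, seedlings of the varieties Xindong20 and Xindong23 were grown in Hoagland nutrient solution with phosphorus at 1.0 mmol/L (conventional phosphorus, CP) or 0.05 mmol/L (low phosphorus, LP), with potassium chloride making up for the potassium phosphate that was left out. After 14 days of culture, all plants were kept in 15% polyethylene glycol (PEG-6000), which withholds water from roots, for 7 days. The solution was changed every 3 days, the light period was 18 h and the temperature was 25 °C by day and 20 °C by night. Every group was therefore under drought, and no unstressed plants were analysed here. Each of the 4 groups had 3 arrays, which the series design describes as biological replicates. Per the labels' protocols, RNA was extracted with Trizol and biotin-labelled cRNA was prepared from 100 ng of total RNA.

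The authors deposited 1 table of normalized values, which are treated here as log2 intensities. Affymetrix Expression Console 1.4.1 and robust multi-array average (RMA) are named in the submitters' processing notes, without role or order. RMA corrects background, sets the arrays to a common distribution and summarises the probes of each probe set, so a change shared by most transcripts would be removed before deposit. The log base was read from the range of the values and is not stated in the sources used here. The probe set library, any filter and the genome build are not given in the sources used here, nor is the order in which arrays were hybridised or scanned. Array medians lay between 4.24 and 4.33. Correlations between arrays ranged from 0.899 to 0.992 and no columns were identical. For arrays there is no read depth, so the number of arrays limits the precision.

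The array carried 61290 probe sets. The 111 control probe sets were left out of the tests, and 61179 were tested without a filter. A platform annotation table paired 1273 of these with exactly 1 gene and none with several, while 59906 had no gene in that table and are unnamed here. Probe set IDs are printed with the character _ in place of the dots of the array's own IDs. Of the 771 genes, 770 were matched to RefSeq by Entrez ID. Only 102 genes, covered by 200 probe sets, had a descriptive symbol or synonym, so most probe sets that passed a test are given as counts. No chromosome positions are given, since the probe sets were not placed on a genome.

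Probe sets were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 12 arrays, which gave 8 residual degrees of freedom and a prior of 2.28 degrees of freedom in the moderated variance. The 6 contrasts were tested, two-sided: LP against CP in Xindong20, the same in Xindong23, the average of both, their difference (the variety by phosphorus interaction), and Xindong20 against Xindong23 at CP and at LP. P-values were adjusted by the Benjamini-Hochberg method over all probe sets tested within a contrast, and a probe set was called at an adjusted p under 0.05. "Rose", "fell", "higher" and "lower" are used of probe sets that passed this test. Fold changes are 2 raised to the difference of group means on the deposited scale. No detection calls were used, so a fold or log2 difference against a group mean below the array medians, where background limits the signal, is read as a lower bound and given as "at least" for a fold. Levels are given as mean ± SD on the log2 scale with 3 arrays per group, unless another n is stated. The p-values rest on the spread between these arrays.

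Which genes the text names was fixed before the data were examined, as were the contrasts, the gene lists and most of the alternative settings. Among nameable probe sets that passed, up to 8 with the largest rise and up to 8 with the largest fall were named per contrast, 1 probe set per gene. Where fewer than 3 passed in a direction, the 3 with the smallest p in that direction are given as values that did not pass. Members of a gene list were to be named where the list was called or 2 or more members passed, and 4 members of the phosphate starvation list were to be given in any case, but that list had no gene on the annotated part of the array. At most 2 unnamed probe sets that rose and 2 that fell are given by their IDs. The exceptions, chosen after their values were seen, are these unnamed probe sets and the other probe sets called in Xindong23. The members quoted from gene lists and the genes given without the low-phosphorus arrays numbered 3 are exceptions too.

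Of 26 gene lists, 14 held at least 1 gene and 2 held at least 5 genes: histones and cell cycle (3 histone H2A genes and 6 tubulin genes, 19 probe sets) and grain storage proteins (9 genes, 14 probe sets, included as a marker of grain tissue). The other 12 with genes were dehydrins and LEA proteins, compatible solutes and fructans, antioxidant enzymes, glutathione S-transferases, lignin and class III peroxidases, cell wall loosening, phytosiderophores and iron, heat shock proteins, pathogenesis-related proteins, auxin and gibberellin, cytosolic ribosomal proteins, and photosynthesis as a marker of shoot tissue. The 12 lists without a named gene were phosphate starvation, abscisic acid, DREB and CBF factors, aquaporins, nitrogen uptake, potassium and chloride transport, low oxygen, jasmonate, ethylene, and the WRKY, NAC and MYB factors, and they gave no result. Each gene was represented by the probe set with the highest mean. The 2 larger lists were tested with camera against the other annotated genes with a preset correlation of 0.01 and again with the correlation estimated, adjusted over both lists. In every list the genes were also adjusted over the list alone. In a list of 1 gene this leaves p unadjusted, and in lists of 2 or 3 genes the adjustment is weak. No adjustment was made over the lists or the contrasts.

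Array quality was read from the control probe sets: the difference between the 3' and 5' probe sets of ubiquitin, glucose-6-phosphate dehydrogenase, sucrose synthase and the added spikes, and the level of 4 poly-A spikes (dap, lys, phe and thr), bacterial transcripts that Affymetrix protocols add to the RNA before labelling. Differences in 12 such tests were compared with exact two-sided permutation tests.

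The fit was tested on simulated data with 200 changed probe sets per contrast. At 2-, 4- and 8-fold changes it recovered 31.4%, 87.1% and 95% in the Xindong20 contrast, with 12 false calls, and 22.9%, 81.4% and 93.3% in the Xindong23 contrast, with 2 false calls. No recovered change had the wrong direction. The simulated noise was independent between arrays, with 1 spread per probe set in all groups. In the real data the median SD between replicates ran from 0.133 to 0.335 by group. Deviations of the low-phosphorus arrays numbered 3 of both varieties correlated at 0.756. These rates therefore need not hold for the real arrays.

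The alternatives fixed beforehand were the replicate number as a block, only the compared groups in the fit, trended and robust variance moderation, array weights, filters on dim probe sets, median centring, quantile normalization, leaving out probe sets whose probes match several transcripts, 1 probe set per gene, other thresholds, other gene set tests, and leaving out each array in turn. Further settings were added after the data were seen: leaving out the low-phosphorus arrays numbered 3 of both varieties, the mean 3' to 5' difference as a covariate, the poly-A spike level as a covariate, and camera with an estimated correlation for the gene list settings that had given a call. All 12 arrays were kept in the reported fit.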

Results

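Root transcript levels were measured in Xindong20 and Xindong23 wheat seedlings held under polyethylene glycol drought for 7 days at conventional (CP) or low (LP) phosphorus, with 3 arrays in each of the 4 groups. Arrays are written by phosphorus level and replicate number, such as CP1 or LP3. The series was designed to ask how the roots of both varieties respond to drought under each phosphorus supply.

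The LP3 arrays of both varieties stood apart from the other 10. On the first principal component, which held 34.7% of the variance, they lay at 174 (Xindong20) and 123.3 (Xindong23), while the others lay between -79.5 and 14.3. Ubiquitin, a constitutive transcript with control probe sets at both ends, had a 3' minus 5' difference of 2.84 (log2) on the Xindong20 LP3 array and 1.16 on the Xindong23 LP3 array, against -0.88 to -0.19 on the others. For glucose-6-phosphate dehydrogenase the values were 6.86 and 6.82, against 2.79 to 4.68. For sucrose synthase they were 7.99 and 8.49, inside the 6.76 to 9.18 of the others, with a 5' probe set that was dim, below the array median, on 11 of 12 arrays. The added spike phe gave 3.55 and 3.47, against 1.26 to 2.0, whereas dap gave 2.62 and 4.74 (others 2.27 to 3.25), lys 0.16 and 1.24 (others 0.08 to 0.68) and thr 1.32 and 3.09 (others 2.29 to 3.50). The 5' probe sets of these 4 spikes were dim on both LP3 arrays, at 1.88 to 3.33. Over all arrays the LP minus CP value of this difference was 0.61 for ubiquitin (exact permutation p = 0.450) and 0.44 for glucose-6-phosphate dehydrogenase (exact permutation p = 0.515). Without the LP3 arrays the values were -0.27 (exact permutation p = 0.0238) and -0.67 (exact permutation p = 0.0190), both with an adjusted p of 0.0714 over 12 tests. The mean level of the 4 poly-A spikes was 6.21 ± 0.89 at LP and 8.05 ± 0.36 at CP (log2, SD, n = 6 each; exact permutation p = 0.00216, 0.0260 after Benjamini-Hochberg adjustment over 12 tests). Without the LP3 arrays it was 6.67 ± 0.47 at LP (n = 4; exact permutation p = 0.00476, adjusted 0.0286). By group it went from 8.20 ± 0.47 at CP to 5.76 ± 0.94 at LP in Xindong20 and from 7.89 ± 0.19 to 6.67 ± 0.68 in Xindong23. Of the 111 control probe sets, 31 had all LP arrays below all CP arrays and 0 had all of them above. The median SD between replicates was 0.181 at CP and 0.335 at LP in Xindong20, and 0.133 at CP and 0.262 at LP in Xindong23.

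**Figure D1:**
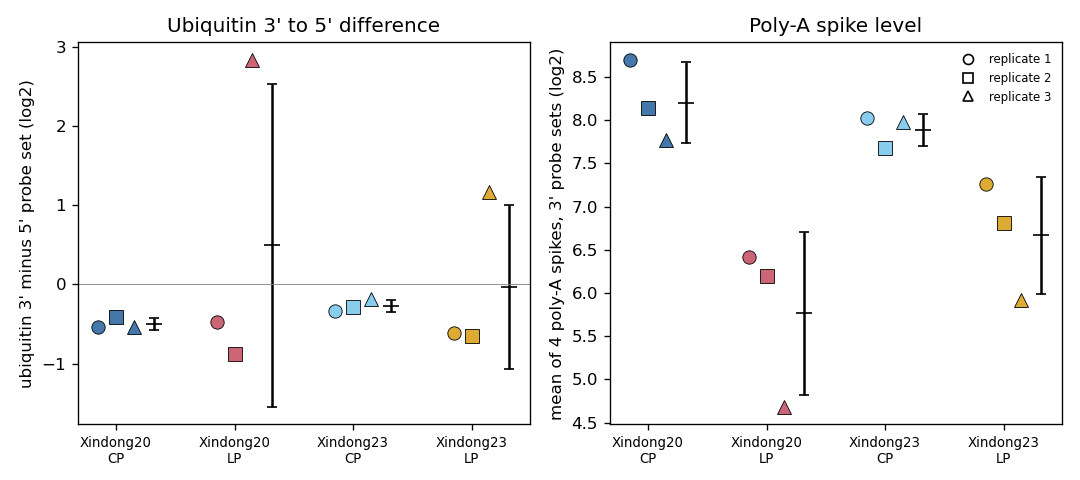
Left, the 3' minus 5' difference of the ubiquitin control (log2) on each array, by group; right, the mean level of the 4 poly-A spikes (log2), with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD of 3 arrays. The LP3 arrays lie at 2.84 and 1.16 on the left, above the range of -0.88 to -0.19 of the other 10, and the spike level on the right averages 6.21 at LP and 8.05 at CP.

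In Xindong20 roots, 2 named genes were lower at low phosphorus, where the poly-A spikes were lower too. SAHH (S-adenosylhomocysteine hydrolase, the enzyme that clears the by-product of methylation reactions; Ta_1258_1_S1_a_at) fell from 13.15 ± 0.09 to 12.27 ± 0.38 (log2 change -0.88, SE 0.18, limma adjusted p = 0.0402), and its other probe set had a change of -1.21. Prx1 (Ta_6572_1_S1_a_at) fell from 3.95 ± 0.15 to 3.05 ± 0.24, near the dim end of the array (-0.90, SE 0.18, limma adjusted p = 0.0374), while of the 4 Prx1 probe sets 2 had positive and 2 negative changes. The largest measured change belonged to the unnamed probe set Ta_6744_2_S1_s_at, which rose at least 281-fold, from 3.74 ± 0.34 to 11.88 ± 1.05 (limma adjusted p = 0.00108). Ta_13989_1_S1_at rose at least 66.4-fold from a dim 3.98 (limma adjusted p = 0.00807), while Ta_18507_1_S1_s_at fell by 4.13 on the log2 scale to a dim 3.08, which makes this a lower bound (limma adjusted p = 0.0142), and Ta_9029_1_A1_at by 4.06 (limma adjusted p = 0.0190). In each of these probe sets all 3 LP arrays lay on the same side of all 3 CP arrays. Chance gives this separation in 10% of cases for a probe set not chosen by its change. These were chosen among the calls, which favours it, so it is no further support.

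Named genes that did not pass in Xindong20 included the histone H2A gene H2A-9 (Ta_27657_12_S1_at; 5.37 ± 0.79 at CP, 7.89 ± 1.17 at LP; 2.52, SE 0.61, limma adjusted p = 0.0671), whose 6 probe sets had changes from 2.38 to 3.28, H2A-3 (Ta_27192_1_S1_at; 1.83, adjusted p = 0.122), whose other probe set had a change of -0.47, WZF1 (Ta_103_1_S1_at; 0.65, adjusted p = 0.0712) and the gibberellin 20-oxidase gene GA20ox1d (Ta_141_1_S1_at; -0.55, adjusted p = 0.0509; called without LP3, -0.60). The histone and cell cycle list had a median change of 0.55 with 6 of 9 genes positive, and the grain storage list one of -0.14 with 2 of 9 positive (3 of 9 with median centring). Camera called neither (adjusted p = 0.158 for both lists; adjusted p = 0.552 with an estimated correlation). No gene of any list passed over all probe sets with its representative probe set. Adjusted over the list alone, 4 genes passed, all with negative changes: CAT1 (catalase; -0.70, SE 0.19, limma p adjusted over the list alone 0.0114), PER1 (-0.49, SE 0.16; 0.0157 among antioxidant enzymes and 0.0209 among peroxidases), 6-FEH (a fructan exohydrolase; -0.52, SE 0.16; 0.0192) and GA20ox1d (Ta_141_1_S1_x_at; -0.53, SE 0.16; 0.0208). Over all probe sets their limma adjusted p-values were 0.0857, 0.130, 0.125 and 0.110. Their lists held 2 or 3 genes, so the adjustment over the list alone is weak. The lists of dehydrins and LEA proteins (LEA 0.04), glutathione S-transferases (GSTZ1 0.40), cell wall loosening (XTH 0.04), phytosiderophores (DMAS1 -0.22), heat shock proteins (hsp16.9A 0.07), pathogenesis-related proteins (Glc1 -1.72), cytosolic ribosomal proteins (CL9 0.19) and photosynthesis (OEE2 0.39) had 0 genes past limma's threshold either way, beside 11332 probe sets of the whole array at an unadjusted p under 0.05. The photosynthesis list had a median of -0.08 and a mean of 0.06, and the medians of the dehydrin and LEA list and of the lignin and peroxidase list, both 0.04, were -0.03 and -0.02 after quantile normalization. On the same arrays the ubiquitin 3' minus 5' difference was 2.84 at LP3, and the poly-A spikes were lower at LP.

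The test called 1072 of 61179 probe sets in Xindong20, 597 higher and 475 lower at LP, of which 620 changed at least 2-fold and 13 at least 16-fold. At an unadjusted p under 0.05 there were 11332, where 3059 would fall by chance. Only 23 of the called probe sets had a gene in the annotation. With median centring the split was 664 higher and 351 lower and with quantile normalization 515 higher and 764 lower. The count was 149 without CP1, 175 without CP2, 201 without CP3, 682 without LP1 and 434 without LP2. Without the LP3 arrays, a setting chosen after the data were seen, it was 4750 (2105 higher, 2645 lower), including 1057 of the 1072. With the poly-A spike level as a covariate, also chosen afterwards, limma called 0, Ta_6744_2_S1_s_at included (7.51, adjusted p = 0.0630, within a range of 8.84e-05 to 0.0630 over its alternatives). With that covariate the change of SAHH was -0.59 (limma adjusted p = 0.256) and that of Prx1 -0.56 (0.264), and with array weights SAHH, still called, was at -0.56. The change of Ta_13989_1_S1_at was 5.30 without LP3, 6.96 without LP2 and 3.38 with the spike covariate, against 6.05 as reported. That of Ta_18507_1_S1_s_at was -4.77 without CP1, -3.27 without CP2 and -4.76 with the covariate, and that of Ta_9029_1_A1_at -4.85 without LP3 and -5.41 with the covariate. Fitted on the Xindong20 arrays alone it called 5 probe sets, with neither SAHH, Prx1, Ta_13989_1_S1_at, Ta_18507_1_S1_s_at nor Ta_9029_1_A1_at among them. SAHH was lost too with trended variance, median centring or 1 probe set per gene, and Prx1 with quantile normalization. SAHH was also lost without CP1 (-0.87), CP2 (-0.93), CP3 (-0.85), LP2 (-0.82) or LP3 (-0.73), Prx1 without CP1 (-0.91), CP2 (-0.82), CP3 (-0.97), LP1 (-0.96), LP2 (-0.98) or LP3 (-0.76), and Ta_9029_1_A1_at without CP1 (-3.97) or CP2 (-3.86).

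In Xindong23 roots, 4 unnamed probe sets rose at low phosphorus and no named gene passed. Ta_6744_2_S1_s_at rose 272-fold, from 4.78 ± 1.22 to 12.87 ± 0.15 (limma adjusted p = 0.00459), and Ta_13989_1_S1_at rose at least 139-fold from a dim 3.72 (limma adjusted p = 0.0278), so its folds in the varieties cannot be ranked. TaAffx_112045_1_S1_at and its partner TaAffx_112045_1_S1_x_at, named because so few passed, each rose by 2.57 (log2; limma adjusted p = 0.0324 and 0.0141). All 4 had also risen in Xindong20, the last pair by 2.18 and 1.80, and the interaction tests gave limma adjusted p-values of 0.990, 0.720, 0.731 and 0.329. In all 4 the 3 LP and 3 CP arrays of Xindong23 did not overlap, as chance gives in 10% of cases with either direction counted for a probe set not chosen by its change. Being called favours such a separation, so it is no further support.

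Among named genes in Xindong23, H2A-9 (Ta_27657_12_S1_at) stood at 7.02 ± 0.47 at CP and 8.81 ± 0.77 at LP (1.80, limma adjusted p = 0.641), with changes of 0.10 to 1.80 over its 6 probe sets. The wheat germ agglutinin gene WGA2 had a change of 1.4 (adjusted p = 0.708; called without LP1, 2.18), Serpin-Z2B one of 0.59 (0.710), rbcl, the large subunit of Rubisco, one of -1.32 (TaAffx_128414_1_A1_x_at; 0.498), H2A-3 one of -0.45 (Ta_27192_1_S1_s_at; 0.843) and DMAS1, which makes the iron-chelating phytosiderophore deoxymugineic acid, one of -0.92 (0.869). SAHH changed by 0.15 and Prx1 by 0.09 in this variety (limma adjusted p = 0.999 each), and the differences from Xindong20 did not pass either (interaction -1.03, adjusted p = 0.121, and -0.99, adjusted p = 0.127). The histone and cell cycle list had a median of 0.15 (6 of 9 positive; camera adjusted p = 0.391; adjusted p = 0.716 with an estimated correlation) and the grain storage list one of 0.13 (7 of 9 positive, 6 of 9 with median centring or quantile normalization; 0.367 and 0.716). Adjusted over the list alone, 1 gene passed, rbcl (Ta_24976_1_S1_x_at; -1.29, SE 0.41, limma p 0.0319 over the list alone, 0.593 over all probe sets), in a list whose median was 0.30 and whose mean was -0.23. The heat shock genes hsp16.9A (1.39) and FKBP70 (0.60) and the LEA gene (0.92) did not pass. The LP3 array of this variety had a ubiquitin 3' minus 5' difference of 1.16.

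The 4 calls in Xindong23 stood beside 3540 probe sets at an unadjusted p under 0.05 in limma, with 3059 by chance. The count was 2 without CP1, 2 without CP2, 1 without CP3 and 0 without LP3, where 6 and 5 were called without LP1 and LP2. Ta_6744_2_S1_s_at was lost without LP3 (8.01), and its change of 8.09 was 7.38 without CP1. Ta_13989_1_S1_at was lost without CP1 (7.29), CP2 (7.15), CP3 (6.92), LP2 (7.03) or LP3 (6.70), TaAffx_112045_1_S1_at without CP1 (2.69), CP2 (2.34), CP3 (2.69), LP1 (2.58), LP2 (2.65) or LP3 (2.49), and TaAffx_112045_1_S1_x_at without CP3 (2.65) or LP3 (2.45). TaAffx_112045_1_S1_at was lost with quantile normalization as well. After leaving out both LP3 arrays 16 were called, the 4 included, and 0 were called with the spike level as a covariate (Ta_13989_1_S1_at at 5.77) or with the Xindong23 arrays alone. With the 3' to 5' difference as a covariate, chosen afterwards too, Ta_13989_1_S1_at changed by 6.28.

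**Figure D2:**
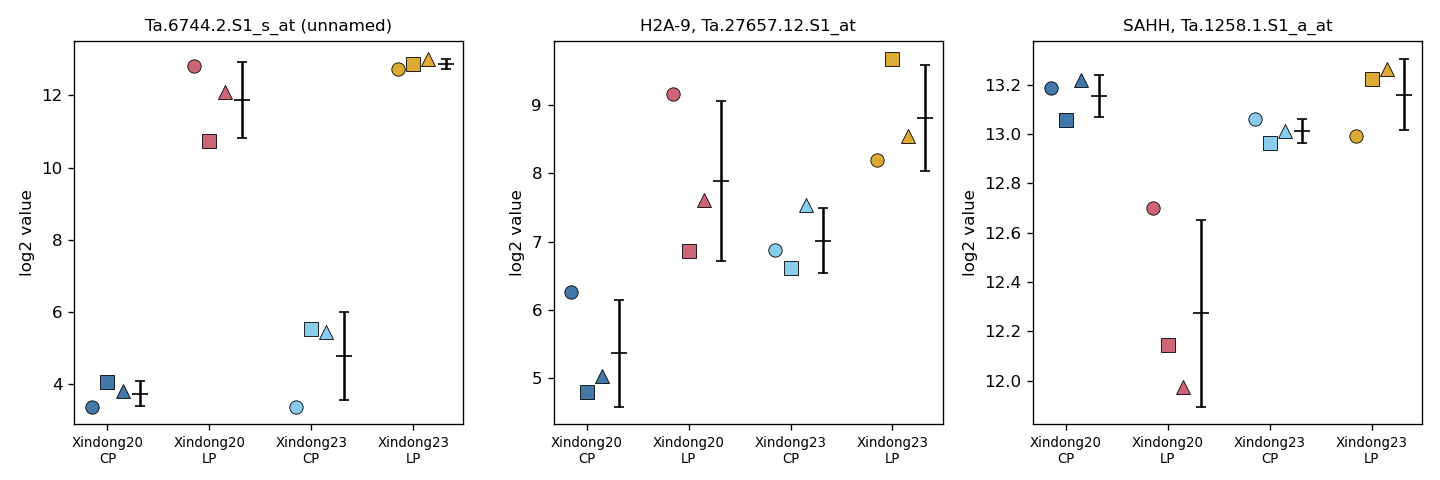
Deposited log2 values per array in the 4 groups for the unnamed Ta_6744_2_S1_s_at, H2A-9 (Ta_27657_12_S1_at) and SAHH (Ta_1258_1_S1_a_at), with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD of 3 arrays. Ta_6744_2_S1_s_at goes from 3.74 to 11.88 in Xindong20 and from 4.78 to 12.87 in Xindong23, H2A-9 from 5.37 to 7.89 and from 7.02 to 8.81, and SAHH from 13.15 to 12.27 in Xindong20 and by 0.15 in Xindong23.

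Averaged over both varieties, Ta_6744_2_S1_s_at was higher at low phosphorus by 8.11 (log2, SE 0.43, limma adjusted p = 0.000144) and Ta_13989_1_S1_at by 6.58 (SE 0.51, limma adjusted p = 0.00127), while Ta_5603_1_A1_at was lower, with a log2 change of -2.46 (SE 0.35, limma adjusted p = 0.0302), as was Ta_21427_1_S1_at, with one of -2.28 (SE 0.23, limma adjusted p = 0.00608). No named gene passed. The histone H2A genes had the smallest p-values upward: H2A-9 (Ta_27657_12_S1_at; 2.16, SE 0.43, limma adjusted p = 0.0889), H2A-3 (Ta_27192_1_S1_at; 1.38, SE 0.40, adjusted p = 0.224) and H2A-2 (1.81, SE 0.54, adjusted p = 0.242). A further H2A-3 probe set (Ta_27192_1_S1_s_at) had a change of -0.46 (adjusted p = 0.241), Prx1 one of -0.40 (0.254) and GA20ox1d one of -0.26 (Ta_141_1_S1_at; 0.280). Adjusted over the list alone, H2A-3 and H2A-2 passed (limma p over the list alone 0.0331 each). The whole histone and cell cycle list, with a median of 0.38 and 6 of 9 genes positive, did not (camera adjusted p = 0.251; adjusted p = 0.794 with an estimated correlation), nor did the grain storage list (median -0.06, 3 of 9 positive; 0.624 and 0.794). The photosynthesis list had a median of 0.11 and a mean of -0.09. The poly-A spikes were lower in the same direction of comparison, at 6.21 against 8.05.

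On average 142 probe sets were called, 84 higher and 58 lower at LP, 91 of them at least 2-fold, with 6623 at an unadjusted p under 0.05. With the LP3 arrays left out 1734 were called (978 higher, 756 lower), all 142 included, and with the spike level as a covariate limma called 0. Ta_13989_1_S1_at changed by 6.0 and 4.58 in these settings. The count was 51 without Xindong20 CP1, 34 without Xindong20 CP3 and, for Xindong23, 39 without CP1, 22 without CP2, 33 without CP3, 290 without LP1, 83 without LP2 and 42 without LP3. Ta_5603_1_A1_at was lost without Xindong20 CP1 (-2.38), CP3 (-2.32) or LP2 (-2.36), or Xindong23 CP2 (-2.48), CP3 (-2.25), LP2 (-2.44) or LP3 (-2.33).

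The responses of the varieties to low phosphorus were weakly related across probe sets, which are not independent replicates. In Xindong23, 3540 probe sets had an unadjusted limma p under 0.05, where 3059 would fall by chance. Noise in these changes lowers any correlation, so a low r does not show unlike responses. The median changes over all probe sets, -0.05 in Xindong20 and 0.03 in Xindong23, also lower the share of equal signs. Pearson's r of the log2 changes was 0.175 over all probe sets and Spearman's rho 0.0257, with the same sign in 47.1%. Among the 1072 probe sets called in Xindong20 r was 0.215, with the same sign in 40.9%. The 4 probe sets that rose in Xindong23 all rose in Xindong20, where independent lists would share 0.039. No arrays were shared between these comparisons, but both used the same variance per probe set. Deviations of the LP3 arrays of both varieties correlated at 0.756, and a pair of partner probe sets is among the 4. The baseline of 0.039 can therefore be too low. Without the Xindong23 LP3 array r over all probe sets was -0.025.

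**Figure D3:**
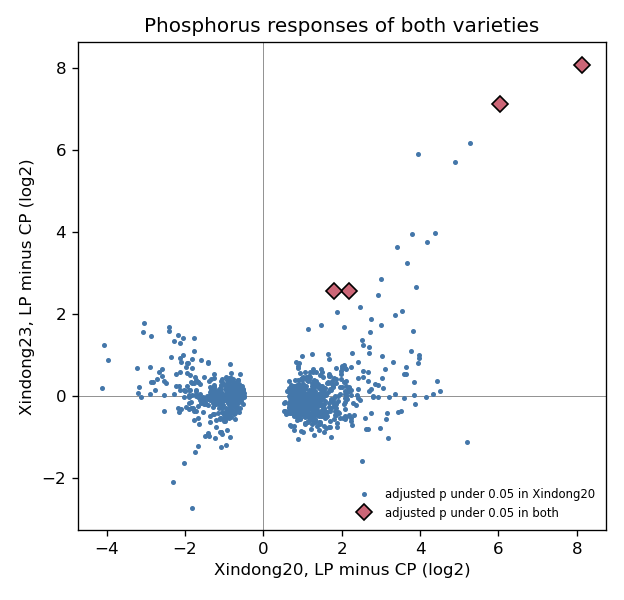
Log2 change at LP relative to CP in Xindong20 (horizontal) and Xindong23 (vertical) for the 1072 probe sets called in Xindong20 (blue dots); red diamonds mark the 4 called in both varieties. The 4 lie at 1.80 to 8.13 in Xindong20 and 2.57 to 8.09 in Xindong23, and r over the 1072 is 0.215.

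The response to low phosphorus differed between the varieties for 81 probe sets, 69 with a positive and 12 with a negative interaction (the Xindong20 change minus the Xindong23 change), and in 72 the change was larger in size in Xindong20. Ta_2870_2_S1_at went from 4.66 to 9.16 in Xindong20 and from 5.35 to 5.48 in Xindong23 (interaction 4.38, SE 0.37, limma adjusted p = 0.00569). TaAffx_80118_1_S1_at went from 3.30 to 8.50 and from 8.95 to 7.83 (6.32, a lower bound since 3.30 is dim, limma adjusted p = 0.0203), Ta_10626_1_A1_at from 10.05 to 6.08 and from 6.81 to 7.70 (-4.86, limma adjusted p = 0.0450), and TaAffx_67846_1_A1_at from 8.52 to 5.48 and from 6.75 to 8.54 (-4.83, limma adjusted p = 0.0455). Among named genes none passed: WZF1 had an interaction of 0.82 (limma adjusted p = 0.158), the ribosomal protein gene RPS29 of 0.67 (0.197), AdSS (adenylosuccinate synthetase) of 0.92 (0.249), rbcl (TaAffx_128414_181_S1_at) of -2.01 (0.0871), SAHH of -1.03 (0.121; called without Xindong20 LP1, -1.24) and Prx1 of -0.99 (0.127). Adjusted over the list alone, CAT1 (-1.02, SE 0.27, limma p 0.00904 over the list alone, 0.137 over all probe sets) and GA20ox1d (Ta_141_1_S1_x_at; -0.65, SE 0.22; 0.0467 and 0.235) passed. Camera called neither the histone and cell cycle list (median 0.66, adjusted p = 0.424; adjusted p = 0.734 with an estimated correlation) nor the grain storage list (median -0.27, 1 of 9 positive, adjusted p = 0.0867; 0.598). The pathogenesis-related list had a median of 0.04, and of -0.02 after quantile normalization.

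Of the 81 interaction calls, 74 had opposite signs in the varieties, 76 were also called in Xindong20 and 0 in Xindong23. In Xindong23 limma called 4 probe sets in all and 3540 had an unadjusted p under 0.05. Being called for the interaction favours opposite signs and a large change in at least 1 variety. The counts of 74 and 76 are therefore no further support for opposite responses. Over all probe sets the sign was the same in 47.1%. With quantile normalization the split was 51 and 21, and median centring gave 193 calls. Leaving out the LP3 arrays gave 571 calls (431 and 140), 77 of the 81 included. Leaving out 1 array of Xindong20 gave 13 (CP1), 8 (CP2), 6 (CP3), 147 (LP1), 19 (LP2) and 206 (LP3), and of Xindong23 11 (CP1), 3 (CP2), 3 (CP3), 37 (LP1), 15 (LP2) and 3 (LP3). Ta_2870_2_S1_at passed under all 23 alternatives (limma adjusted p 0.00155 to 0.0389). TaAffx_80118_1_S1_at was lost without Xindong20 CP3 (6.09) or Xindong23 CP2 (6.22), CP3 (6.23) or LP3 (6.37), and Ta_10626_1_A1_at (-5.14 to -4.38) and TaAffx_67846_1_A1_at (-5.30 to -4.47) were lost without any 1 array except Xindong20 LP3 and with trended variance, the former also with the spike level as a covariate. Without Xindong20 LP3 they were -5.48 and -5.44, and the latter was -5.49 with that covariate.

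At conventional phosphorus, Xindong20 and Xindong23 roots differed at 1 named gene by the test. A probe set of rbcl (TaAffx_128414_181_S1_at) was higher in Xindong20, at 8.07 ± 0.38 against 6.61 ± 0.26 (1.47, SE 0.30, limma adjusted p = 0.0340), and the 28 rbcl probe sets had 17 positive and 11 negative differences. The largest measured differences were of unnamed probe sets, each dim in 1 variety, so that their sizes are lower bounds and are not ranked: Ta_5824_2_S1_at stood at 11.17 ± 0.47 in Xindong20 and 3.15 ± 0.30 in Xindong23 (at least 260-fold, limma adjusted p = 2.15e-06), Ta_3242_3_A1_at was at least 172-fold higher (7.81e-07), and Ta_1151_1_S1_at (-6.47, limma adjusted p = 0.000282) and Ta_11179_1_A1_at (-6.03, 7.41e-06) were lower in Xindong20. All 3 Xindong20 arrays lay on the same side of all 3 Xindong23 arrays in these 5 probe sets, as chance gives in 10% of cases for a probe set not chosen by its difference. Their choice among the calls favours this, so it is no further support. Prx1 (0.76, limma adjusted p = 0.0548), GA20ox1d (Ta_141_1_S1_at; 0.44, 0.0934), the TATA-binding protein gene TBP1 (-0.93, 0.109), RPS29 (-0.45, 0.149) and AdSS (-0.66, 0.170) did not pass. Adjusted over the list alone, 6-FEH (0.55, SE 0.16, limma p 0.0136 over the list alone, 0.113 over all probe sets), the LEA gene (1.99, SE 0.62; 0.0271 and 0.130) and PR5, a thaumatin-like pathogenesis-related protein (2.76, SE 0.87; 0.0296 and 0.135), passed with positive values. The histone and cell cycle list had a median of -0.86 (2 of 9 positive, 3 of 9 after quantile normalization) and the grain storage list one of 0.15 (8 of 9 positive, 6 of 9 with either other scaling), each with a camera adjusted p of 0.0902 (adjusted p = 0.429 with an estimated correlation). The heat shock and the lignin and peroxidase lists had medians of 0.01 each, and of -0.06 and -0.05 with median centring.

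The variety test at CP called 1438 probe sets, 547 higher and 891 lower in Xindong20, 954 of them at least 2-fold and 86 at least 16-fold, with 10807 at an unadjusted p under 0.05. With median centring the split was 425 and 1128, and with quantile normalization 581 and 604. Without the LP3 arrays, which enter only the shared variance here, 6221 were called (2663 and 3558), all 1438 included. The count was 707, 485 and 761 without CP1, CP2 and CP3 of Xindong20, and 556, 403 and 458 without CP1, CP2 and CP3 of Xindong23. The rbcl probe set was lost without Xindong20 CP2 (1.31) or CP3 (1.41) or Xindong23 CP1 (1.60), CP2 (1.45) or CP3 (1.34).

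At low phosphorus no named gene passed between the varieties. Ta_5824_2_S1_at was again higher in Xindong20, at 11.68 ± 0.27 against 3.19 ± 0.61 (at least 359-fold, limma adjusted p = 2.03e-06), with its partner Ta_5824_2_S1_x_at (at least 163-fold, 7.65e-06), while Ta_1912_1_S1_at (-6.46, limma adjusted p = 0.000896) and Ta_1151_1_S1_at (-6.23, 0.000420) were lower, the former not called in a fit on the LP arrays alone. Values that did not pass included 1 of the 6 H2A-9 probe sets (Ta_27657_14_S1_s_at; 4.03, SE 0.82, limma adjusted p = 0.0586), whose other probe sets went both ways, lgul (0.79, 0.0971), GSTZ1 (TaAffx_56524_1_S1_at; a glutathione transferase; 1.47, 0.117), SAHH (-0.89, 0.0528), Eif4B, a translation initiation factor (-0.55, 0.188), and CAT1 (-0.64, 0.234). Leaving out Xindong20 LP1 made SAHH (-1.10), GSTZ1 (1.81) and H2A-9 (2.94) calls, and leaving out Xindong20 LP2 the H2A-9 probe set (4.73). The rbcl probe set called at CP had a difference of -0.55 at LP (limma adjusted p = 0.729; interaction -2.01, adjusted p = 0.0871). Adjusted over the list alone, PR5 (2.82, SE 0.87, limma p 0.0260 over the list alone, 0.279 over all probe sets), GSTZ1 (Ta_237_1_S1_a_at; 0.91, SE 0.34; 0.0247 and 0.462) and CAT1 (-0.64, SE 0.19; 0.0187 and 0.234) passed. The list of GSTZ1 held 1 gene, so its limma p of 0.0247 is unadjusted, and those of PR5 and CAT1 held 3 genes each. The histone and cell cycle list (median -0.34, 1 of 9 positive) and the grain storage list (median -0.06, 3 of 9 positive) each had a camera adjusted p of 0.250 (adjusted p = 0.627 with an estimated correlation).

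The variety test at LP called 550 probe sets, 349 higher and 201 lower in Xindong20, 504 at least 2-fold and 61 at least 16-fold, with 5077 at an unadjusted p under 0.05. Without the LP3 arrays 843 were called (533 and 310), 438 of the 550 included, and without Xindong20 LP3 alone the count was 876. Ta_1912_1_S1_at was -5.43 without Xindong23 LP1 and -7.11 without its LP2, and Ta_1151_1_S1_at -5.57 without Xindong23 LP2, -6.95 without its LP3 and -7.03 without both LP3 arrays. Both phosphorus levels shared 172 probe sets higher in Xindong20 and 119 lower, where independent lists would share 3.12 and 2.93, and 7 were called in opposite directions. Both tests used the same variance per probe set, so these baselines can be too low.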

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

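Chosen only after the results were seen were both tests on the arrays that stood apart, the tests of those arrays and of the replicate spread as causes of the gap between varieties, and the settings that leave out the LP3 arrays or use the spike level as a covariate.

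The response to low phosphorus differed between the varieties, by limma's interaction test, for 81 probe sets, with differences of at least 6.32 for TaAffx_80118_1_S1_at, which was dim at CP in Xindong20, 4.38 for Ta_2870_2_S1_at, -4.86 for Ta_10626_1_A1_at and -4.83 for TaAffx_67846_1_A1_at. In 2 of 100 drawn splits of the phosphorus labels within varieties, the real one included, the count was as large. The highest other split gave 142, and exchanges the labels of 1 variety, which turns the real average into the interaction. Such splits remove any phosphorus response from both varieties. They argue against a chance arrangement of the labels, but cannot test an interaction apart from a response common to both varieties. The count was also 3 to 206 with 1 array left out and 6 with the replicate block.

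The LP3 arrays of both varieties differed from the other 10. Their lower ubiquitin 3' minus 5' difference exceeded the highest of the others by 1.35 (log2), where the others had an SD of 0.20, and glucose-6-phosphate dehydrogenase stood apart likewise, which is consistent with loss of the 5' part of these labelled transcripts; sucrose synthase lay inside the range of the others, but its 5' probe set, dim on 11 of 12 arrays, leaves little room for a loss to be measured. A response of the plants that left the added spikes unchanged is argued against. The mean 5' level of the spikes, at 2.77 and 2.79, lay at least 1.43 below the lowest of the others (SD 0.86). The 3' minus 5' difference of phe (3.55 and 3.47, others up to 2.0) stood above them by more than 3 SD on both arrays. Of the 4 spikes only phe did so. On the Xindong20 LP3 array dap (2.62) and lys (0.16) lay inside the range of the others and thr (1.32) below it. On the Xindong23 LP3 array dap (4.74) and lys (1.24) lay above that range and thr (3.09) inside it. On both arrays the 5' probe sets of all 4 spikes (1.88 to 3.33) were dim, below the array median. A spike difference inside or below the range therefore does not show that a 5' loss was absent. A larger share of plant RNA would lower all 4 spikes alike, but the 3' level of dap (5.18 and 7.79) lay below all of the others (8.66 or more), as did those of thr and lys, which loss of the 5' part alone would not give, while that of phe (6.20 and 6.80) lay within them. What led to the difference, and whether the plants of these samples also differed, was not settled.

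Low phosphorus called 1072 probe sets in Xindong20 and 4 in Xindong23. The LP3 arrays are argued against as the cause of that gap, since without them 4750 and 16 were called, a ratio of 297. The median SD between replicates in Xindong23 was 0.769 of that in Xindong20 (0.224 against 0.291). A larger spread in Xindong23 is therefore not what these medians show. The fit shared 1 variance, with a median SE of 0.216 in both varieties. At a typical probe set that SE is small for the spread of Xindong20 and large for that of Xindong23, which favours calls in Xindong20. By group the median SD was 0.181 at CP and 0.335 at LP in Xindong20, and 0.133 and 0.262 in Xindong23. Fitted on the compared groups alone, with fewer residual degrees of freedom, limma called 5 probe sets in Xindong20 and 0 in Xindong23. Between the varieties at CP such a fit called 8733, against 1438 as reported. How far the shared variance made the gap was not settled. A labelling difference that tracks the poly-A spikes cannot be told apart from phosphorus: with the spike level as a covariate 0 probe sets were called in either variety, which decides nothing, since the level moves with phosphorus, from 8.20 to 5.76 in Xindong20 and from 7.89 to 6.67 in Xindong23, and among the 1072 the median absolute change went from 1.11 to 0.83 while the median SE went from 0.196 to 0.333, with the same direction in 100%. With that covariate limma's interaction test still called 49 probe sets, 26 of the 81 among them, with Ta_2870_2_S1_at at 4.11 (adjusted p = 0.0273), so a difference in response between the varieties remains an open hypothesis beside it.

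The counts for 3 against 3 arrays have 10 splits, too few for a share under 0.05: the real and highest other counts were 1072 and 9 in Xindong20 (1 split as large, the real one), 4 and 1 in Xindong23 (1), 1438 and 9 between varieties at CP (1), and 550 and 1475 between varieties at LP (3). At LP the larger splits, 866 and 1475, put both LP3 arrays in the same group, which points to a structure of the samples, although 2 other such splits gave 0 calls in limma. For the average response 1 of 100 drawn splits, the real one, gave as many as 142, with 81 as the highest other, which argues against a chance arrangement of the labels.

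At both phosphorus levels 177 probe sets differed at least 4-fold between the varieties, 107 higher and 70 lower in Xindong20. Of the pairs with another probe set of the same sequence cluster, 23.8% (24 pairs) followed in direction and with at least 1/4 of the size, against 49.3% (34 of 69) for the phosphorus calls of at least 4-fold in Xindong20 (Fisher's exact test, two-sided p = 0.000906). This is consistent with sequence differences between the varieties under single probe sets, as a technical part of the pattern, though pairs from 40 and 33 clusters are not independent. Expression of 1 gene copy alone, or a copy missing in 1 variety, was not tested and stays open.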

How the results depend on the processing

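The settings without the LP3 arrays, with a covariate, and with an estimated correlation for the list calls were chosen after the data were seen. Counts are given in the order LP against CP in Xindong20, in Xindong23, on average, the interaction, and the varieties at CP and LP (1072, 4, 142, 81, 1438 and 550 as reported). Of 142 alternative counts 98 differed by over 1.5 times and 44 did not; the reported calls that a setting tested kept their direction in it, though some settings tested few (19 of the 1072 with 1 probe set per gene, 799 at a mean of at least 5). Array weights gave 16449, 32, 2690, 4208, 12120 and 1177. Leaving out the LP3 arrays gave 4750, 16, 1734, 571, 6221 and 843, the 3' to 5' covariate 3434, 15, 355, 2332, 4283 and 1005, and the spike covariate 0, 0, 0, 49, 2715 and 1028, where limma's unadjusted counts were 11332, 3540 and 6623 without it. An unadjusted p under 0.05 with 2-fold gave 2504, 570, 770, 2886, 2476 and 1723, an adjusted p under 0.01 gave 78, 1, 23, 3, 409 and 294. One probe set per gene gave 8, 1, 0, 5, 9 and 2, with far fewer tested. Other counts that moved were 5, 0, 8733 and 127 with only the compared groups (Xindong20, Xindong23, CP and LP), 538, 81, 14 and 942 with trended variance (Xindong20, average, interaction and CP), 620, 91 and 954 with a 2-fold minimum (Xindong20, average and CP), 9, 914 and 354 at a mean of at least 5 and 8 at or above the median (Xindong23, CP and LP; Xindong23), 2 without shared probe sets (Xindong23) and 193 with median centring (interaction). The cause was not tested.

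Leaving out each array in turn gave ranges of 149 to 1381, 0 to 6, 22 to 290, 3 to 206, 403 to 761 and 382 to 876. Replicate numbers did not pair the arrays throughout. Of 18 same-numbered pairs, 6 had a correlation of deviations over 0.1 (-0.287 to 0.756, the highest for the LP3 arrays of both varieties). Of 12 arrays, 5 correlated best with their own number. With the replicate block the counts were 857, 0, 66, 6, 1121 and 514, and SAHH, rbcl, the 4 calls in Xindong23 and all named interaction calls but Ta_2870_2_S1_at were not called.

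With all probe sets of the list genes camera called histones and cell cycle in Xindong20 (0.00241), on average (0.00651), for the interaction (0.0214) and at CP (0.00885), and gave the opposite direction at LP (0.956). These calls used the preset correlation; with an estimated one the adjusted p was 0.580, 0.667, 0.565 and 0.661, and 0.985 at LP, again opposite. The grain storage list was called without the LP3 arrays in Xindong20 (0.0115; adjusted p = 0.128 with an estimated correlation) and the interaction (0.0381; adjusted p = 0.205 with an estimated correlation), and turned direction in Xindong23 without them (0.865; adjusted p = 0.928 with an estimated correlation) and at LP at a mean of at least 5 (0.890). The other 85 list results kept direction and side. Agreement between the varieties (r = 0.175) was 0.745 over the probe sets called on average, a selection that favours changes alike in both varieties and so says nothing on agreement, and -0.025 to 0.334 with 1 array left out. Of 1144 alternatives for 60 named results, 992 kept direction and side, 46 passed where the reported value had not, 106 lost a call and 0 changed direction. Levels near 3 to 4, such as Prx1, lie at the dim end of these arrays, where background limits how far a fall, or a rise from such a level, can be measured.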

Other observations

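All values of the first paragraph and the histone test come from tests chosen after the data were seen. Without the LP3 arrays, the spikes (6.67 at LP against 8.05 at CP) and bioB still differed between the phosphorus levels. In that setting Pgk-1 (a phosphoglycerate kinase) was higher at LP in Xindong20 (0.91, SE 0.17, limma adjusted p = 0.0243). So were AGP-S (the small subunit of ADP-glucose pyrophosphorylase, which feeds starch synthesis, 1.15, SE 0.24, 0.0325) and PCM (1.64, SE 0.35, 0.0334). UBC1 (a ubiquitin-conjugating enzyme, 0.83, 0.0316), NCBP (0.81, 0.0360) and WZF1 (0.50, 0.0447) were higher too. The reported changes with all arrays were 0.40, 0.68, 1.11, 0.07, 0.08 and 0.65, and of these probe sets none passed; with the poly-A spike level as a covariate on all arrays limma called 0 probe sets in Xindong20, and WZF1 was at 0.07 (adjusted p = 0.852). GA20ox1d (-0.60, limma adjusted p = 0.0250), ATI (-0.76, 0.0277), a probe set of rbcl (TaAffx_128414_15_S1_at; -0.87, 0.0198), both SAHH probe sets (-0.73 and -0.82, 0.0389 and 0.0462) and Prx1 (-0.76, 0.0394) were lower. For these the reported changes with all arrays were -0.55, -0.52, -0.48, -0.88, -1.21 and -0.90. Of them only the former SAHH probe set and Prx1 passed with all arrays. On average over the varieties Pgk-1 (0.86, limma adjusted p = 0.0170), eIF-2-beta (0.76, 0.0228), PRO1 (profilin; 0.89, 0.0244), NCBP (0.77, 0.0256) and UBC1 (0.70, 0.0298) were higher, where the reported averages with all arrays were 0.46, 0.34, -0.18, 0.18 and 0.13 and none passed. In these fits each LP group keeps 2 arrays.

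Between the varieties at CP the same setting, in which only the shared variance changes, called TBP1 (-0.93, limma adjusted p = 0.00491) and PRO1 (1.27, 0.00636) among 10 genes, and at LP a probe set of rbcl (TaAffx_128414_1_A1_x_at; 1.23, 0.0493). With all arrays TBP1 (limma adjusted p = 0.109), PRO1 (0.564) and the rbcl probe set at LP (1.14, 0.335) did not pass.

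H2A-2, H2A-3, H2A-9, wcH2B-6 and wcH2B-8 had positive changes in both varieties at the probe set with the highest mean of each gene, with an average of 0.83 to 2.07 and a median of 1.52. The other H2A-3 probe set (Ta_27192_1_S1_s_at) went the opposite way, at -0.47 in Xindong20 and -0.45 in Xindong23. These 5 genes were put together after their values were seen, so a test on them decides nothing. Camera gave p = 0.000232 with the preset correlation and 0.112 with an estimated one (0.871), and without the LP3 arrays 0.0148 and 0.296 (estimated correlation 0.942). No single gene passed over all probe sets, and the histone and cell cycle list fixed beforehand was not called on average (adjusted p = 0.251, and 0.794 with an estimated correlation). Whether a coordinated rise of the named histone genes at low phosphorus took place was not settled.

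The bioB hybridisation control stood at 7.90 ± 0.89 at LP and 8.22 ± 0.33 at CP over all arrays (log2, n = 6 each, exact permutation p = 0.435). Without the LP3 arrays it stood at 7.37 ± 0.26 at LP (n = 4, exact permutation p = 0.00476, 0.0286 after Benjamini-Hochberg adjustment over 12 tests). On the LP3 arrays bioB was at 9.38 (Xindong20) and 8.56 (Xindong23), while the mean 3' level of the poly-A spikes there was 4.68 and 5.92.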
